A study of Sus scrofa with 3 samples.

How the data were processed

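Total RNA from the livers of 3 male pigs was sequenced as paired-end reads on an Illumina HiSeq instrument, with 1 library for each of 3 breeds, per the labels' protocols. The deposited files give whole-number read counts per gene, 1 table per library, not normalized. The submitters' processing notes name TopHat2 2.1.0, HTSeq 0.6.1, edgeR 3.16.3 and the genome build Sscrofa10.2. The annotation release, the strand setting, the treatment of reads that align to several places and whether the library kit marks strand are not given in the sources used here. Reads that fell on several features were set apart in each deposited file and counted for no gene. Reads of near-identical copies, overlapping genes and antisense genes could therefore have been dropped or misassigned, and such genes are treated as uncertain.

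Each table had 25322 gene IDs and 5 rows that name no gene, which stayed out of library sizes and comparisons. Of all reads assigned to a gene, to no feature or to several features, those with no feature made up 19.0% in Enshi black, 22.0% in Large White and 18.9% in Chinese wild boar, and ambiguous reads 1.89%, 2.18% and 2.49%. Totals over genes were 20654571, 19982627 and 20215871 counts, with 16192, 16761 and 16964 gene IDs detected, and the 10 most abundant IDs took 22.4%, 23.6% and 21.8% of counts. At this depth 1 count was worth 0.0463, 0.0512 and 0.0505 CPM (a gene's count scaled to a common library total), and a floor of 3 counts 0.139, 0.154 and 0.152 CPM. Symbols were matched by gene ID for 11804 IDs, and 7101 IDs had no count in any library. No genome of the build was given, so no coordinates are reported.

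Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (1.04, 0.978 and 0.979). Genes with at least 1 CPM in at least 1 library were kept, leaving 13228, of which 8756 had a symbol. With 1 library per breed there is no test across animals and no p-value: a comparison of counts compares these libraries, not the breeds. For each pair of libraries, the fold of scaled counts was given with a 95% exact conditional binomial (Clopper-Pearson) interval, computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. No molecular identifiers are described in the labels, so intervals and floors cover counting error only. A gene passed the size rule when the interval bound nearest to 1 was at least 2 or at most 0.5. It stood apart in a library when it passed in the same direction against both others. A fold against a library with no count is given as at least its interval bound nearest to 1.

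A set of 35 gene lists was fixed before the data were examined. For the 32 lists with at least 3 expressed members, the median log2 fold (prior count 2) was placed among 10000 random lists of the same size, drawn from named expressed genes in 20 bins of mean expression. This percentile describes these libraries and is not a test, and of 96 such medians 4.8 would lie outside the central 95% by chance if lists were random, against 41 observed. Several genes belong to more than 1 list, so lists are not independent. The 3 comparisons also share libraries, and genes of a list can vary together, unlike the unrelated genes of random lists. The excess over 4.8 therefore does not measure chance. None of the symbols of the sex-linked list matched a gene ID, so the labels could not be checked by sex, and many MHC, P450 and conjugating enzyme genes had no matched ID.

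The genes named were set by a rule fixed before the data were examined. It took, per comparison, the 6 genes with a symbol per direction whose near bound lay farthest from 1. Per list it took 1 to 4 passing members by near bound or, where none passed, up to 2 abundant members. Per library it took the 4 genes per direction that stood apart most, and overall the 10 most abundant gene IDs, of which 7 had a symbol. MLXIPL, as the 1 lower gene of its list, and EGR1, as the 1 higher gene of its list, were named after their values were seen. Some genes that the rule takes are not reported here.

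The size rule was tested on simulated data, with 200 of 13228 genes changed per comparison. For Enshi black against Large White it recovered 89 of 100 genes changed 4-fold and 98 of 100 changed 8-fold, for Chinese wild boar against Large White 93 and 100, and for Enshi black against Chinese wild boar 95 and 100. The simulated counts carry counting noise only, with no variation between animals. The alternatives tried were DESeq2 1.42.0 size factors, total counts, no expression filter, a filter of 10 CPM, near bounds of 1.5 and 4, a 99.9% interval, and a normal interval that adds an assumed coefficient of variation of 0.2 or 0.4 between animals. For lists a prior count of 0.5 and the mean in place of the median were tried too. Under total counts the median log2 fold of all expressed genes was 0.10 for Enshi black against either other library, against 0.01 with TMM.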

Results

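Liver RNA was sequenced from 3 male pigs at postnatal day 90, with 1 library for each of 3 breeds. Enshi black is a Chinese local breed, Large White is a European commercial breed, and the third animal was a Chinese wild boar. The series is described as a study of the porcine liver transcriptome during development, but the libraries share 1 age, so the comparisons available are between breeds. The deposited tables held 20654571 gene counts for Enshi black, 19982627 for Large White and 20215871 for Chinese wild boar. Of 25322 gene IDs, 13228 were expressed, with a CPM (the gene's count scaled to a common library total) of at least 1 in at least 1 library, and 8756 of these had a gene symbol. The labels name 3 pigs and 3 libraries and do not mention pooling, which is read here as 1 animal per library. On that reading, breed, animal and library cannot be separated, and no difference given here has a replicate check. Every interval in parentheses after a fold is a 95% exact binomial interval that covers counting error only. A gene passed the size rule when the bound of that interval nearest to 1 was at least 2-fold away.

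Of the 10 gene IDs of highest mean abundance, 3 had no symbol, and the 7 with a symbol were genes of secreted plasma proteins. Albumin (ALB) had 66508 CPM in Enshi black, 25310 in Large White and 53648 in Chinese wild boar. Apolipoprotein E (APOE) had 14670, 39379 and 24810 CPM in the same order, and apolipoprotein C-III (APOC3) had 9489, 21017 and 21642. Transferrin (TF) had 23596, 21018 and 18137 CPM, fetuin A (AHSG) 13744, 9099 and 15141, and fibronectin (FN1) 13156, 7615 and 5364. Complement component C3 had 17267, 16809 and 6329 CPM.

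The first comparison asked how the Enshi black liver differed from that of Large White. Some genes of cholesterol and of fatty acid synthesis were higher in Enshi black, although most members of both lists did not pass. The cholesterol synthesis gene HMGCS1 was 5.10-fold higher (4.87 to 5.34), and the fatty acid desaturases FADS1 and FADS2 were 5.87-fold (5.59 to 6.16) and 4.70-fold (4.42 to 5.0) higher. All 19 expressed proliferation genes lay above 0 on the log2 scale under each of 3 scalings, though only 4 passed, and collagen COL3A1 was 3.60-fold higher (3.49 to 3.72). Lower genes included IGFBP1, a binding protein of insulin-like growth factors, by 31.4-fold (28.3 to 34.9), C-reactive protein (CRP) by 6.32-fold (6.18 to 6.46) and the macrophage receptor CSF1R by 7.12-fold (6.35 to 8.01).

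In all, 621 genes passed the size rule as higher in Enshi black than in Large White and 1110 as lower, or 13.1% of the 13228 expressed genes. Ranked by the bound nearest to 1, the leading higher genes included GABRQ, LEPR, ALOX15, PGGHG and MMRN2. LEPR, the leptin receptor, was 52.1-fold higher (39.3 to 70.6), and MMRN2, an endothelial matrix protein, 34.3-fold (17.9 to 75.7). GABRQ (238-fold, 42.4 to 9441), ALOX15 (131-fold, 35.9 to 1085) and PGGHG (196-fold, 34.9 to 7796) had only 1 or 2 counts in Large White. Among the lower genes, BANF1 and GNB2 had no count in Enshi black and were at least 391-fold and at least 156-fold lower by the interval bound. MT3, annotated as a metallothionein, was 417-fold lower (311 to 572), and ZNF251, PHLDB1 and C2orf68 had 1 to 3 counts in Enshi black, giving ratios of 698 (125 to 27614), 341 (116 to 1654) and 575 (103 to 22772). In the Enshi black library alone, 47 gene IDs had 3 counts or fewer while both other libraries had at least 5 CPM, against 1 such ID in each of the other libraries.

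Among the lipid lists, 18 fatty acid and triglyceride synthesis genes were expressed, of which 4 passed higher, 1 lower and 13 neither way, with a median log2 fold of 0.59. Besides the desaturases, the elongase ELOVL2 was 22.3-fold higher (11.6 to 49.5) and ACLY, which makes cytosolic acetyl-CoA, 2.87-fold (2.63 to 3.13), while the transcription factor MLXIPL was 2.09-fold lower (2.03 to 2.16) and did not pass with total counts. Of 20 cholesterol synthesis and uptake genes, 5 passed higher and 1 lower (median 0.45), with SQLE 4.88-fold (4.50 to 5.29) higher but the isomerase IDI1 8.38-fold lower (6.52 to 10.9). Of 23 fatty acid oxidation and ketogenesis genes, 1 passed higher and 3 lower (median 0.47). ACAA2 and BDH1, enzymes of beta-oxidation and ketone body formation, were 3.65-fold (3.45 to 3.86) and 3.58-fold (3.27 to 3.94) lower, and the 1 higher member, ACADVL, was 7.92-fold higher (2.83 to 30.7) at few counts. Of 16 bile acid genes, 2 passed higher and 3 lower (median -0.08). KLB, the FGF coreceptor beta-klotho, was 8.32-fold higher (7.25 to 9.58), and AKR1D1, a bile acid and steroid reductase, 3.63-fold lower (3.33 to 3.97). Of 18 lipoprotein and lipid droplet genes, 1 passed higher and 3 lower (median 0.03): APOB was 2.91-fold higher (2.83 to 3.0) and APOE 2.68-fold lower (2.67 to 2.70).

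In carbohydrate, growth factor and amino acid metabolism, list medians lay inside the central 95% of random lists while single members differed widely. Of 18 glucose and glycogen genes, 2 passed higher and 3 lower (median 0.01): PPP1R3B, a glycogen-targeting phosphatase subunit, was 5.46-fold higher (5.22 to 5.70), and GPT2, an alanine aminotransferase, 4.08-fold lower (3.75 to 4.45). Of 12 growth hormone and IGF axis genes, 1 passed higher and 3 lower (median -0.23). IGFALS, the acid-labile subunit of the circulating IGF complex, was 4.18-fold lower (3.94 to 4.44) and IGF1 itself 2.78-fold lower (2.25 to 3.46), while the prolactin receptor PRLR was 5.05-fold higher (3.43 to 7.66). Of 25 urea cycle and amino acid catabolism genes, 1 passed higher and 5 lower (median -0.18), led by the glutaminase GLS2 at 45.0-fold (31.2 to 67.5) and the histidine ammonia-lyase HAL at 6.73-fold (6.01 to 7.56) lower.

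Among secreted and defence proteins, 16 hepatocyte secreted protein genes gave 1 higher and 2 lower (median 0.20), with ALB 2.63-fold higher (2.62 to 2.64) and the fibrinogen chain FGB 4.53-fold lower (4.44 to 4.62). Of 11 acute phase genes, 1 passed higher and 3 lower (median -0.10): LCN2 was 5.65-fold higher (4.07 to 8.02) and ITIH4 3.13-fold lower (3.10 to 3.17). Of 29 complement and coagulation genes, 2 passed higher and 1 lower (median -0.21), with the lectin MBL2 4.88-fold higher (4.55 to 5.23). Of 23 interferon response genes, 4 passed higher and none lower (median 0.53), among them IFI44 at 2.91-fold (2.59 to 3.28) and USP18 at 2.86-fold (2.48 to 3.31). TAP2, a peptide transporter and 1 of 2 expressed members of the MHC class I list, was 4.28-fold higher (2.79 to 6.82). None of 5 MHC class II genes passed (median -0.02).

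The cytochrome P450 and FMO drug metabolism list also holds other genes, such as aldehyde oxidase AOX1. Of its 11 expressed genes only AOX1 passed, 2.27-fold higher (2.22 to 2.33), with a list median of 0.43. Of 8 genes of the conjugating enzyme list, which also holds the epoxide hydrolase EPHX1, 1 passed higher and 2 lower (median 0.04). The glutathione transferases GSTA4 and GSTM3 were 4.58-fold higher (4.18 to 5.02) and 19.6-fold lower (7.33 to 73.9). Of 10 steroid, androstenone and skatole metabolism genes, the oestrogen receptor ESR1 passed higher at 2.84-fold (2.35 to 3.46) and AKR1D1 lower (median 0.28). Of 9 iron and metallothionein genes, BMP6, an inducer of hepcidin, was 6.81-fold higher (6.15 to 7.54) and MT3 lower (median 0.19). Of 14 circadian clock genes, 2 passed higher and 3 lower (median 0.33), including BMAL1 at 3.75-fold lower (2.68 to 5.32) and BHLHE41 at 3.55-fold higher (2.25 to 5.81).

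Of the 19 proliferation genes, 4 passed higher and none lower (median 0.94, percentile 100 among random lists). They were the cyclins CCNB1 at 4.0-fold (2.96 to 5.49) and CCNB2 at 3.99-fold (2.34 to 7.22), CENPF at 2.80-fold (2.5 to 3.14) and TOP2A at 2.23-fold (2.0 to 2.5). TOP2A did not pass with DESeq2 size factors. Of 18 immediate early genes, 4 passed lower and none higher (median -0.59), with CCN1 5.25-fold (4.73 to 5.84) and JUNB 4.49-fold (4.12 to 4.90) lower. Of 17 heat shock genes, 2 passed higher (median 0.47): HSPA1L, a member of a family of near-identical copies, was 3.06-fold higher (3.0 to 3.11), and DNAJB1 2.96-fold (2.65 to 3.30). Of 16 unfolded protein and amino acid stress genes, only asparagine synthetase ASNS passed, 6.56-fold higher (4.62 to 9.58), with a list median of -0.10.

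Cell type markers differed in direction. Of 20 stellate cell and fibroblast markers, 8 passed higher and none lower (median 0.88, percentile 100), including the collagen cross-linking enzyme LOX at 10.1-fold (6.80 to 15.6) and COL1A2 at 3.55-fold (3.25 to 3.88). Of 14 Kupffer cell and macrophage markers, 5 passed lower and none higher (median -0.67, percentile 0.11), among them LYZ at 6.67-fold (4.35 to 10.6) and the scavenger receptor MARCO at 3.97-fold (3.58 to 4.41). Of 5 neutrophil markers, 3 passed lower (median -1.26), led by CSF3R at 5.62-fold (4.65 to 6.84). None of 19 T and NK cell markers passed (median -0.11), and of 9 B and plasma cell markers 3 passed higher and 1 lower (median 0.45), with CD79B 5.48-fold higher (3.35 to 9.43) and POU2AF1 4.75-fold lower (3.35 to 6.88). Of 14 endothelial markers, MMRN2 passed higher and STAB1, a sinusoidal scavenger receptor, lower by 2.68-fold (2.59 to 2.79), with a median of 0.03. Of 3 erythroid markers, haemoglobin HBB passed lower by 2.80-fold (2.58 to 3.05), with a median of -0.09. None of 10 cholangiocyte markers passed (median -0.08), and the pancreatic enzyme CPA1, the 1 expressed member of the muscle and pancreas list, had no count in Enshi black. Of 13 mitochondrially encoded genes, only ATP8 passed, 3.70-fold lower (3.15 to 4.38), with a median of 0.04. Of 21 ribosomal protein genes, 2 passed higher and 2 lower (median 0.52), with RPS16 2.33-fold higher (2.19 to 2.49) and RPS23 4.38-fold lower (4.06 to 4.73).

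With an assumed coefficient of variation of 0.4 between animals added to the counting error, 126 genes passed higher and 399 lower, and 28 of 119 named or listed genes kept passing, among them LEPR, IGFBP1 and CSF1R. Of list members that passed higher, 1 each did among fatty acid and triglyceride synthesis, cholesterol, bile acid, and iron and metallothionein genes. The same held among unfolded protein and amino acid stress genes, endothelial markers, and stellate cell and fibroblast markers. Of list members that passed lower, 2 each did among conjugating enzyme genes, urea cycle and amino acid catabolism genes, and Kupffer cell and macrophage markers. Among acute phase, cholesterol, growth hormone and IGF axis, iron and metallothionein, and muscle and pancreas genes, 1 each did. Lists with at least 3 passing genes that kept none were proliferation, immediate early, interferon response, fatty acid oxidation, lipoprotein, glucose, secreted protein, complement, clock, ribosomal protein, neutrophil and B cell genes. Over 10 equal groups by RefSeq span of genes with a symbol and at least 5 CPM in both other libraries, the median log2 fold of Enshi black against their mean rose from -0.21 in the shortest group to 0.14 in group 9 and 0.09 in the longest, and folds here are not corrected for this trend. MT3, HSPA1L, the GST, RPS and RPL genes and other genes with copies or overlapping neighbours are uncertain. The counting of reads that align to several places and the strand setting are not given in the sources used here.

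**Figure D1:**
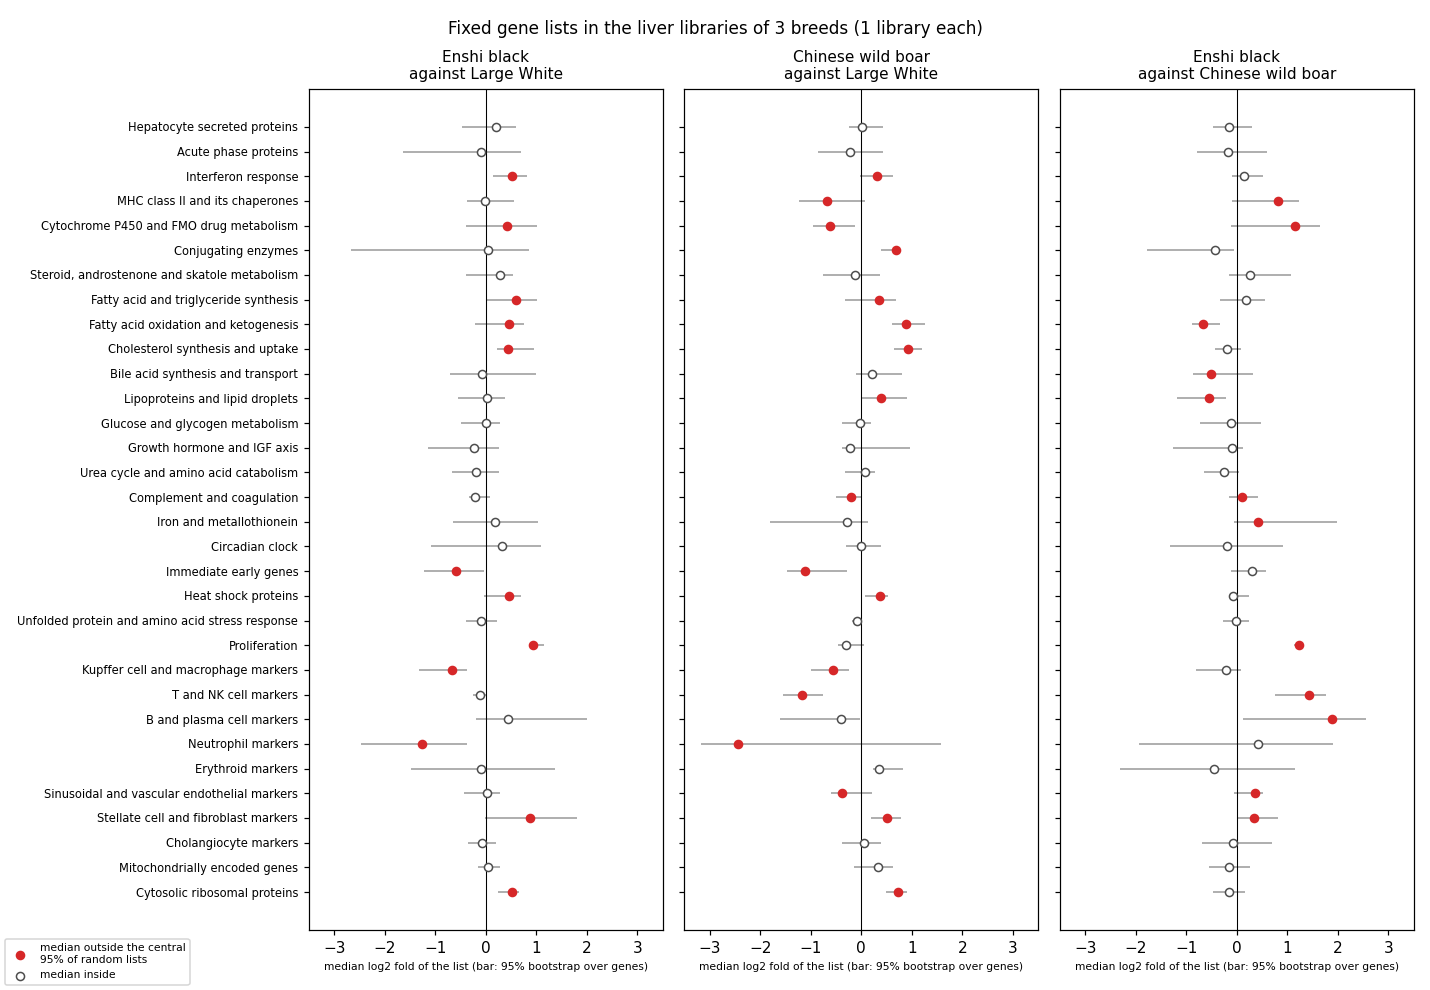
Median log2 fold of the 32 gene lists with at least 3 expressed members (vertical axis) in each of the 3 comparisons (horizontal axis, log2 scale), with bars giving the 95% bootstrap range over the genes of a list. Filled points are the 41 of 96 medians outside the central 95% of matched random lists, such as fatty acid oxidation at 0.88 in Chinese wild boar against Large White.

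The second comparison set the Chinese wild boar liver against that of Large White. Genes of fatty acid oxidation and of cholesterol synthesis were higher in Chinese wild boar: 10 of 23 expressed fatty acid oxidation and ketogenesis genes and 8 of 20 cholesterol genes passed higher, and none passed lower. CPT1A, the carnitine transferase that controls entry of fatty acids into mitochondria, was 3.44-fold higher (3.28 to 3.62), and the liver hormone FGF21 was 18.3-fold higher (11.9 to 29.6). CYP7A1, the rate-limiting enzyme of bile acid synthesis, was 5.71-fold lower (5.13 to 6.36). Some markers of T and NK cells and of neutrophils were lower, with CD8A at 7.45-fold (5.73 to 9.83) and the receptor CSF3R at 7.53-fold (6.03 to 9.51) lower.

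Here 391 genes passed as higher and 495 as lower, or 6.70% of the expressed genes. The leading higher genes included PGGHG at 228-fold (40.5 to 9049, with 1 count in Large White), ABCC8, ELOVL2, VIL1 and DHRS7C. ABCC8, a sulfonylurea receptor, and DHRS7C had no count in Large White and were at least 39.1-fold and at least 15.0-fold higher. ELOVL2 was 41.9-fold higher (21.8 to 92.4) and the microvillus protein VIL1 23.8-fold (19.9 to 28.7). The leading lower genes were TENM4, MT3, ELF3, SLC34A2, LUZP2 and BSPH1. MT3 was 38.1-fold lower (34.7 to 42.0) and the epithelial transcription factor ELF3 22.6-fold (18.1 to 28.7). TENM4, the phosphate transporter SLC34A2 and LUZP2 had no count in Chinese wild boar and were at least 49.7-fold, 17.1-fold and 15.1-fold lower. BSPH1, with 3 counts, had a ratio of 42.5 (14.2 to 209).

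The fatty acid oxidation list had a median log2 fold of 0.88 (percentile 100). Its members included HADHA, part of the mitochondrial trifunctional protein, at 4.41-fold (4.23 to 4.6) and CPT2 at 3.38-fold (3.17 to 3.59) higher. All 20 cholesterol genes lay above 0 (median 0.93, percentile 100), with SQLE 4.39-fold (4.05 to 4.76) and HMGCS1 3.27-fold (3.11 to 3.43) higher. Of 18 fatty acid and triglyceride synthesis genes, 3 passed higher (median 0.36): ELOVL2, FADS1 at 4.16-fold (3.96 to 4.38) and FADS2 at 3.52-fold (3.30 to 3.76). Of 18 lipoprotein and lipid droplet genes, G0S2, an inhibitor of lipolysis, passed at 4.30-fold (3.95 to 4.69) and the lipid droplet protein CIDEC at 4.57-fold (3.71 to 5.68) higher, with a median of 0.38. Of 16 bile acid genes, 2 passed higher and 1 lower (median 0.21): besides CYP7A1, the repressor NR0B2 was 3.95-fold higher (3.54 to 4.41) and KLB 2.78-fold (2.38 to 3.24).

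Of 18 glucose and glycogen genes, 1 passed higher and 3 lower (median -0.02). The bifunctional glycolytic regulator PFKFB3 was 8.71-fold lower (7.09 to 10.8), and pyruvate carboxylase (PC) 2.26-fold higher (2.21 to 2.32). Of 12 growth hormone and IGF axis genes, 2 passed higher and 1 lower (median -0.21): IGFBP1 was 4.62-fold lower (4.41 to 4.83) and PRLR 3.70-fold higher (2.47 to 5.68). None of 25 urea cycle and amino acid genes passed (median 0.07).

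Of 11 genes of the cytochrome P450 and FMO drug metabolism list, FMO5 passed lower at 2.52-fold (2.42 to 2.63). The list median was -0.62 (percentile 0.01). None of 8 genes of the conjugating enzyme list passed, although their median was 0.68 (percentile 99.7). Its epoxide hydrolase EPHX1 had a ratio of 1.58 (1.55 to 1.61). None of 10 steroid, androstenone and skatole genes passed (median -0.12), with CYP2E1, which degrades skatole, at a ratio of 0.652 (0.643 to 0.661). Of 16 secreted protein genes, FETUB at 2.51-fold (2.42 to 2.60) and ALB at 2.12-fold (2.11 to 2.13) passed higher (median 0.02). Of 11 acute phase genes, CRP at 2.20-fold (2.17 to 2.23) and STEAP4 at 2.42-fold (2.11 to 2.79) passed lower (median -0.22). Of 29 complement and coagulation genes, MBL2 passed higher at 4.65-fold (4.34 to 5.0) and C3, the central complement component, lower at 2.66-fold (2.64 to 2.67), with a median of -0.21.

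Of 19 T and NK cell markers, 7 passed lower and none higher, and all 19 lay below 0 (median -1.17, percentile 0). The kinase LCK was 4.21-fold lower (3.30 to 5.43) and CD6 6.96-fold lower (4.76 to 10.5). Of 5 neutrophil markers, 3 passed lower, CSF3R among them (median -2.44). Of 9 B and plasma cell markers, MZB1 passed lower at 4.39-fold (3.12 to 6.29), with a median of -0.40. Of 14 Kupffer cell and macrophage markers, MARCO passed lower at 2.94-fold (2.67 to 3.24), with a median of -0.56, and of 14 endothelial markers STAB1 at 2.97-fold (2.85 to 3.09), with a median of -0.39. Haemoglobin HBB had a ratio of 1.78 (1.68 to 1.88), and none of 3 erythroid markers passed (median 0.35). Of 20 stellate cell and fibroblast markers, LOX at 4.97-fold (3.27 to 7.82) and COL1A2 at 2.76-fold (2.52 to 3.02) passed higher (median 0.50). None of 10 cholangiocyte markers passed (median 0.05), and CPA1 had a ratio of 0.614 (0.369 to 1.01).

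Of 18 immediate early genes, 7 passed lower and 1 higher (median -1.12, percentile 0). The transcription factor MYC and the matricellular gene CCN1 were 3.34-fold (3.05 to 3.66) and 3.32-fold (3.03 to 3.64) lower, and the 1 higher gene was EGR1 at 2.21-fold (2.08 to 2.36). None of 19 proliferation genes passed (median -0.30). Of 17 heat shock genes, DNAJB1 at 3.23-fold (2.89 to 3.61) and BAG3 at 2.49-fold (2.39 to 2.60) passed higher (median 0.37). Of 16 unfolded protein and amino acid stress genes, the serine synthesis enzyme PHGDH passed higher at 2.65-fold (2.44 to 2.88) and ATF3 lower at 2.67-fold (2.28 to 3.15), with a median of -0.09. Of 23 interferon response genes, MX1 passed higher at 2.28-fold (2.15 to 2.41) and GBP2 lower at 2.93-fold (2.36 to 3.64), with a median of 0.32. TAP2 was 3.84-fold higher (2.47 to 6.15), and none of 5 MHC class II genes passed (median -0.68). Of 9 iron and metallothionein genes, MT3 and the iron exporter SLC40A1, at 3.59-fold (2.55 to 5.14), passed lower (median -0.28). Of 14 clock genes, RORA passed higher at 2.70-fold (2.37 to 3.08), with a median of 0.00. Of 13 mitochondrially encoded genes, 3 passed higher and 1 lower (median 0.32), with ND1 2.71-fold higher (2.68 to 2.75) and ATP8 5.39-fold lower (4.43 to 6.60). All 21 ribosomal protein genes lay above 0 (median 0.72), and 3 passed, led by RPL14 at 2.39-fold (2.29 to 2.5).

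With an assumed coefficient of variation of 0.4 between animals, 72 genes passed higher and 97 lower. Of 93 named or listed genes, 19 kept passing, among them FGF21, CD8A and CSF3R, and of the 10 fatty acid oxidation genes only FGF21 did. Lists with at least 3 passing genes that kept none were cholesterol, immediate early, bile acid, growth hormone and IGF, mitochondrially encoded and ribosomal protein genes.

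**Figure D2:**
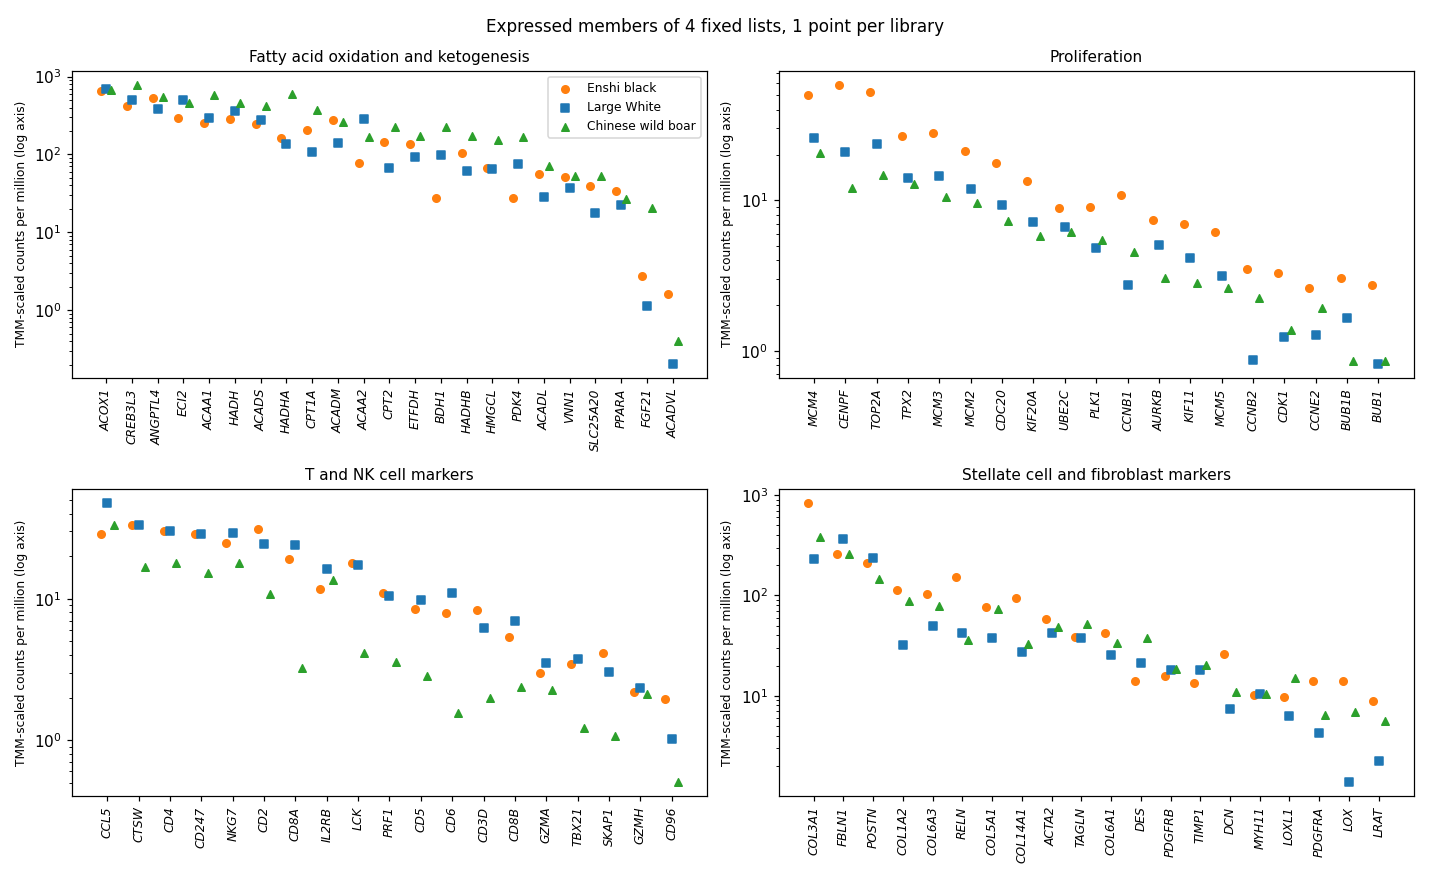
TMM-scaled CPM (vertical log axis) of each expressed member of 4 gene lists (horizontal axis, ordered by mean abundance), with 1 point per library and a marker per breed. Chinese wild boar lies below Large White in all 19 T and NK cell markers, and Enshi black lies above both others in all 19 proliferation genes.

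The third comparison set Enshi black against Chinese wild boar. Genes of fatty acid oxidation were lower in Enshi black, where 7 of 23 passed lower and none higher, while PFKFB3, a regulator of glycolysis, was 14.4-fold higher (11.8 to 17.7). PDK4, a kinase that restrains pyruvate oxidation, was 5.95-fold lower (5.45 to 6.5) and FGF21 7.42-fold lower (5.65 to 9.90). Some lymphocyte markers were higher, with CD8A at 5.92-fold (4.54 to 7.82) and the B cell antigen MS4A1 at 9.17-fold (3.97 to 26.0). All 19 proliferation genes lay above 0 under each of 3 scalings (median 1.24, percentile 100), and the drug-metabolising enzymes AOX1 and FMO5 were 4.62-fold (4.47 to 4.78) and 4.55-fold (4.37 to 4.73) higher.

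A total of 533 genes passed as higher in Enshi black and 939 as lower, or 11.1% of the expressed genes. The leading higher genes were HRH1, PFKFB3, ZBTB32, MMRN2, RNF181 and NECTIN1. The histamine receptor HRH1, RNF181 and the adhesion protein NECTIN1 had no count in Chinese wild boar and were at least 20.2-fold, 10.7-fold and 9.99-fold higher. ZBTB32, with 1 count there, had a ratio of 65.1 (11.3 to 2607), and MMRN2 was 17.4-fold higher (10.8 to 29.7). The leading lower genes were BANF1, at least 473-fold, and GNB2, at least 118-fold. They were followed by C2orf68, PHLDB1, ZNF251 and DENND2D, which had 1 to 3 counts in Enshi black. Their ratios were 557 (99.6 to 22057), 274 (93.3 to 1331), 485 (86.7 to 19214) and 449 (80.2 to 17792). The first 5 of the leading lower genes are among the 47 gene IDs near absent from the Enshi black library alone.

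The fatty acid oxidation list had a median of -0.68 (percentile 0.02). BDH1, which forms the ketone body beta-hydroxybutyrate, was 8.19-fold lower (7.51 to 8.94) and HADHA 3.77-fold lower (3.63 to 3.92). Of 18 lipoprotein and lipid droplet genes, 1 passed higher and 6 lower (median -0.55), with APOB 2.92-fold higher (2.84 to 3.01) and G0S2 3.63-fold lower (3.37 to 3.93). Of 18 fatty acid and triglyceride synthesis genes, fatty acid synthase (FASN) at 2.82-fold (2.76 to 2.89) and LPIN1 at 2.78-fold (2.34 to 3.32) passed higher (median 0.18). Of 20 cholesterol genes, IDI1 at 23.9-fold (18.8 to 30.8) and MVK at 3.82-fold (3.66 to 3.99) passed lower (median -0.19). Of 16 bile acid genes, 3 passed higher and 2 lower (median -0.51): CYP7A1 was 3.53-fold higher (3.2 to 3.95) and AKR1D1 3.54-fold lower (3.24 to 3.87).

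Of 18 glucose and glycogen genes, 4 passed higher and 3 lower (median -0.11), with glycogen synthase GYS2 3.97-fold higher (3.76 to 4.19) and PPP1R3B 3.26-fold higher (3.15 to 3.38). Of 12 growth hormone and IGF axis genes, 3 passed lower (median -0.10): IGFBP1 at 6.80-fold (6.10 to 7.61), IGF1 at 5.95-fold (4.90 to 7.27) and IGFALS at 3.61-fold (3.40 to 3.83). Of 25 urea cycle and amino acid genes, 1 passed higher and 3 lower (median -0.25), with GLS2 33.3-fold lower (23.0 to 49.998). Of 11 genes of the cytochrome P450 and FMO drug metabolism list, 6 passed higher and none lower (median 1.16, percentile 100). They included FMO1 at 3.14-fold (3.07 to 3.22). Of 8 conjugating enzyme genes, 1 passed higher and 3 lower (median -0.43), with GSTM3 lower at a ratio of 32.2 (12.2 to 120.05) and NNMT 3.45-fold lower (3.09 to 3.85). Of 10 steroid, androstenone and skatole genes, 2 passed higher, among them CYP2E1 at 2.24-fold (2.21 to 2.27), and AKR1D1 lower (median 0.26).

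Of 19 T and NK cell markers, 8 passed higher and none lower (median 1.43, percentile 100), with LCK 4.30-fold higher (3.38 to 5.53). Of 9 B and plasma cell markers, 5 passed higher and 1 lower (median 1.89), the lower one being POU2AF1 at 7.28-fold (5.21 to 10.4). Of 5 neutrophil markers, 1 passed higher and LTF lower at 4.14-fold (2.51 to 7.16), with a median of 0.41. Of 14 Kupffer cell and macrophage markers, CSF1R at 3.57-fold (3.15 to 4.04) and CLEC4F at 2.82-fold (2.60 to 3.06) passed lower (median -0.22). Haemoglobin HBB was 4.99-fold lower (4.62 to 5.40), and the 3 erythroid markers had a median of -0.44. Of 14 endothelial markers, MMRN2 and the VEGF receptor KDR, at 2.74-fold (2.56 to 2.92), passed higher (median 0.35). Of 20 stellate cell and fibroblast markers, 4 passed higher and 1 lower (median 0.35), with RELN 4.19-fold higher (3.87 to 4.55) and DES 2.67-fold lower (2.33 to 3.06). Of 10 cholangiocyte markers, SPP1 passed higher at 2.41-fold (2.02 to 2.88) and 1 passed lower, with a median of -0.07. CPA1 passed lower, with no count in Enshi black.

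Of the 19 proliferation genes, 5 passed higher and none lower, with CENPF 4.87-fold (4.24 to 5.62) and TOP2A 3.56-fold (3.13 to 4.06) higher. Of 18 immediate early genes, NR4A3 passed higher at 5.40-fold (2.64 to 12.4) and EGR1 lower at 5.35-fold (4.92 to 5.84), with a median of 0.31. Of 17 heat shock genes, HSPA1L passed higher at 2.60-fold (2.55 to 2.64) and HSPA8 lower at 3.43-fold (3.18 to 3.69), with a median of -0.08. Of 16 unfolded protein and amino acid stress genes, ASNS passed higher at 6.47-fold (4.57 to 9.39) and SEL1L at 2.16-fold (2.0 to 2.32), with a median of -0.02, and SEL1L did not pass with DESeq2 size factors. Of 23 interferon response genes, 3 passed higher (median 0.14), among them GBP2 at 2.79-fold (2.26 to 3.47). Of 5 MHC class II genes, SLA-DMA passed higher at 2.36-fold (2.02 to 2.77), with a median of 0.82, while TAP2 had a ratio of 1.12 (0.851 to 1.47). Of 16 secreted protein genes, FGB at 3.88-fold (3.80 to 3.95) and APOC3 at 2.28-fold (2.27 to 2.29) passed lower (median -0.15). Of 11 acute phase genes, 2 passed higher and 2 lower (median -0.18), with STEAP4 3.94-fold higher (3.47 to 4.50) and CRP 2.87-fold lower (2.80 to 2.94). Of 29 complement and coagulation genes, C3 passed higher at 2.73-fold (2.71 to 2.75), with a median of 0.11. Of 9 iron and metallothionein genes, 3 passed higher and 1 lower (median 0.42), with SLC40A1 6.52-fold higher (4.75 to 9.16) and BMP6 3.98-fold higher (3.67 to 4.31). Of 14 clock genes, 2 passed higher and 4 lower (median -0.18), with BMAL1 4.93-fold lower (3.57 to 6.94). Of 13 mitochondrially encoded genes, ND2 at 4.21-fold (4.14 to 4.29) and ND1 at 2.69-fold (2.65 to 2.72) passed lower (median -0.15). Of 21 ribosomal protein genes, 4 passed lower (median -0.15), led by RPS23 at 9.74-fold (9.07 to 10.5).

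With an assumed coefficient of variation of 0.4 between animals, 108 genes passed higher and 352 lower, and 26 of 127 named or listed genes kept passing, among them PFKFB3, BDH1, FGF21 and IGFBP1. Lists with at least 3 passing genes that kept none were T and NK cell, proliferation, cytochrome P450 and FMO, lipoprotein, bile acid, clock, acute phase, interferon response, steroid and stellate cell genes, and of the 7 lower fatty acid oxidation genes 2 did.

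A gene stood apart in a library when it passed in the same direction against both others. In Enshi black, 226 genes stood apart as higher and 607 as lower. The leptin receptor LEPR had 131 CPM against 2.51 in Large White and 13.1 in Chinese wild boar, and MMRN2 had 15.8 against 0.461 and 0.910, while RNF181 and HRH1 had 45 and 83 counts against at most 2 elsewhere. BANF1, GNB2, C2orf68 and PHLDB1 led the lower genes; BANF1, which binds chromatin at the nuclear envelope, had 66.9 CPM in Large White, 80.9 in Chinese wild boar and no count in Enshi black. In Large White, 224 genes stood apart as higher and 141 as lower. MT3 had 869 CPM against 2.09 in Enshi black and 22.8 in Chinese wild boar, and the axonemal genes DNAH1 and MNS1 had 2284 and 199 counts against at most 138 and 9, while SLC34A2 was counted in Large White alone. Among the lower ones, ELOVL2 had 0.461 CPM in Large White against 10.3 and 19.3, PGGHG 0.0512 against 10.1 and 11.7, and GTSF1 0.154 against 3.66 and 5.56. In Chinese wild boar, 158 genes stood apart as higher and 117 as lower. The short-chain dehydrogenase DHRS4, which has close copies, had 1524 CPM against 119 in Enshi black and 149 in Large White, and ABCC8, MAP6 and DHRS7C had 7.48, 3.99 and 2.93 CPM with at most 3 counts elsewhere. Among the lower ones, the paraoxonase PON3 had 5.10 CPM against 54.8 and 56.2, SPINK5 0.0505 against 2.73 and 2.35, and ZBTB32 0.0505 against 3.29 and 2.25.

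Independent lists of the same lengths would share 25 higher and 78.8 lower genes for Enshi black, 41.5 and 18.4 for Large White, and 27.8 and 19.9 for Chinese wild boar. Libraries simulated with counting noise and no change shared 0 genes in each case, a value that leaves out differences between animals. The comparisons behind each count share a library, so part of the excess may come from that library, which cannot be split.

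**Figure D3:**
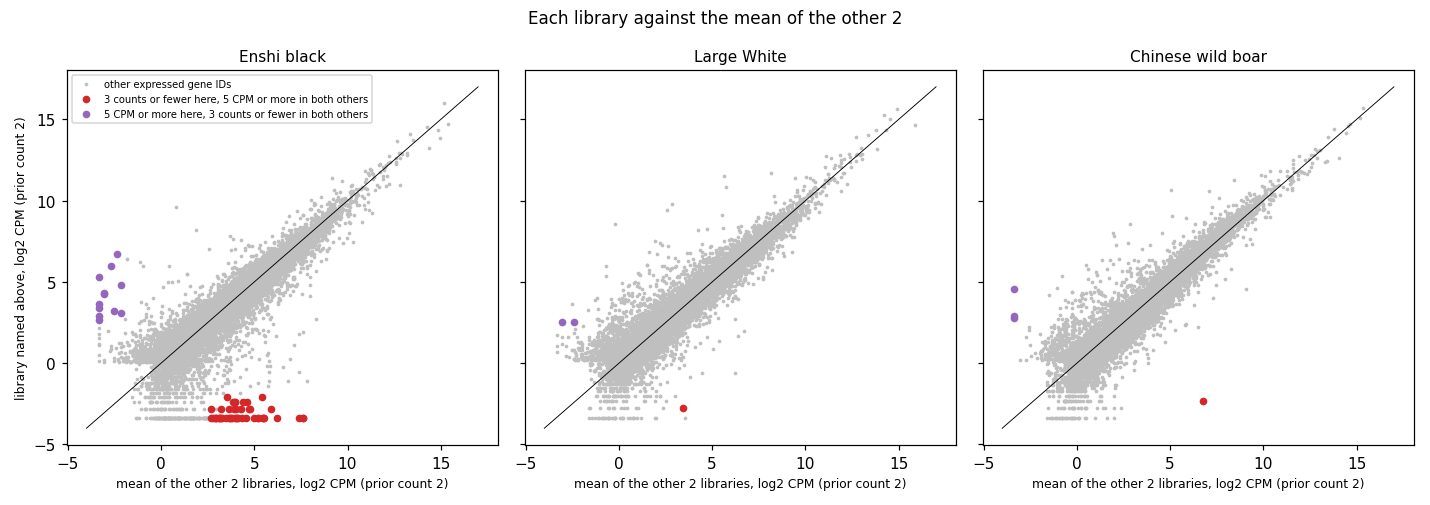
Log2 CPM (prior count 2) of each expressed gene ID in 1 library (vertical axis, a panel per library) against the mean of the other 2 libraries (horizontal axis), with a line of equality. The IDs with 3 counts or fewer in the library named and at least 5 CPM in both others number 47 in Enshi black, 1 in Large White and 1 in Chinese wild boar.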

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

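The settings without the near-absent gene IDs, without the Enshi black library and with the trend over gene span taken off were chosen after seeing the data. No paired analysis was possible because each breed has 1 library, so the groups share 1 replicate number, and for the same reason no replicate could be left out. Counts follow in the order higher and lower for Enshi black against Large White, Chinese wild boar against Large White, and Enshi black against Chinese wild boar, then genes standing apart as higher and lower in Enshi black, Large White and Chinese wild boar. DESeq2 size factors, total counts, no expression filter, leaving out the near-absent IDs and, for Chinese wild boar against Large White, scaling without Enshi black kept each count within 1.5 times its main value. A near bound of 1.5 gave 1531, 1972, 979, 1141, 1303 and 1673, then 625, 1015, 534, 412, 376 and 335. A near bound of 4 gave 150, 444, 87, 114, 117 and 390, then 62, 281, 56, 31, 30 and 21. An assumed variation of 0.2 gave 268, 649, 153, 211, 240 and 559, then 103, 387, 104, 55, 56 and 47, and one of 0.4 gave 126, 399, 72, 97, 108 and 352, then 59, 262, 46, 24, 22 and 19. A filter of 10 CPM, which tests fewer genes, gave 374, 604, 254, 288, 313 and 507, then 133, 318, 131, 95, 102 and 75. The wider exact interval gave 406, 821, 279, 306, 315 and 728, then 151, 454, 149, 91, 110 and 56. These moves follow from wider intervals, another bound or, with the filter, from genes left out and the scaling computed anew. Of 339 fold values of named or passing list genes, 337 kept passing with DESeq2 size factors, 328 with total counts and 290 with the wider exact interval. With an assumed variation of 0.2, 158 did, and with 0.4, 73 did. None changed direction, which was nearly fixed in advance. These genes were chosen at least 2-fold from 1, and the settings mostly widened intervals or shifted the scaling slightly. Of 41 list medians outside the central 95% of random lists, none changed sign under any of the 7 alternatives tried, and 38 could be computed with the filter of 10 CPM. The median of the proliferation list in Enshi black against Chinese wild boar left its bootstrap range of 1.14 to 1.26, moving from 1.24 to 1.33 with total counts, 1.31 with that filter and 1.42 without the span trend, and the others stayed within theirs. Without the span trend 40 of the 41 lay outside the central 95%, the exception being endothelial markers in that comparison (percentile 97.45). In the same comparison 4 other lists came to lie outside it. This setting kept only genes with a RefSeq span, and that alone put the steroid list there outside, at percentile 99.88. Bile acid genes with a span lay inside there, at 5.85, before the trend was taken off and at 0.48 after. Of genes with a RefSeq span, 297 of 332, 486 of 551, 202 of 214, 264 of 278, 256 of 298 and 382 of 436 kept passing, in the order above. Without replicates, differences between animals of a breed remain unmeasured, and depth limits genes near 3 counts.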

Other observations

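The tests of reads moved between gene IDs, of scaling shifts and of residual blood were chosen after the result was seen. A further set of 28 PPAR-alpha target genes outside the fixed lists had 20 expressed members. In Chinese wild boar against Large White 4 of them passed higher and none lower: HSD17B10 at 3.84-fold (3.64 to 4.05), the retinol saturase RETSAT at 3.73-fold (3.47 to 4.02), the peroxisomal and mitochondrial isomerase ECH1 at 2.80-fold (2.5 to 3.13) and the carnitine transferase CROT at 2.29-fold (2.19 to 2.41). In Enshi black against Chinese wild boar 4 passed lower and none higher, with a median log2 fold of -0.51, and in Enshi black against Large White 3 passed higher and 2 lower, with a median of 0.01. The glycerol channel AQP9 was 4.16-fold lower (3.98 to 4.35) in Enshi black than in Large White. With an assumed coefficient of variation of 0.2 between animals, 2 of this set passed higher in Chinese wild boar against Large White, and with 0.4 none did. In Enshi black against Chinese wild boar none passed with 0.2. These genes were chosen outside the rule for named genes.

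Of 23 fatty acid oxidation genes, 10 passed higher in the Chinese wild boar library than in Large White and none lower, and 1 passed with an assumed variation of 0.4 between animals. In Enshi black against Large White the list also had a raised median, 0.47 (percentile 99.94), with 14 of 23 genes above 0, though 1 passed higher and 3 lower. Part of the pattern may therefore lie in the Large White library. Against Chinese wild boar the Enshi black median was -0.68. A shift of scaling was excluded as the whole cause, since it moves all genes alike. In Chinese wild boar against Large White the list's median log2 fold exceeded that of all expressed genes by 0.88 (bootstrap 0.61 to 1.26, n = 23 genes). Its percentile of 100 among random lists of the same libraries is the value given above, not a separate test. A fasting-like state of the animal may account for part of the pattern. The PPAR-alpha targets had a median log2 fold of 0.70 (bootstrap 0.15 to 0.88, n = 20 genes), at percentile 100 of random lists. Members such as the carnitine transferase CROT serve fatty acid oxidation too, so this set cannot separate fasting from breed or another cause. In the comparison with Large White, IGFBP1, which rises in fasting, was 4.62-fold lower, against a fasting-like state. The cholesterol synthesis genes, with a median of 0.93 there, also stand against it. However, IGFBP1 passed lower in Enshi black than in Chinese wild boar, the direction of a fasting-like Chinese wild boar. The cholesterol median was 0.45 in Enshi black against Large White and -0.19 in Enshi black against Chinese wild boar. Part of both values may therefore lie in the Large White library, so they do not decide. Feeding before sampling is not given in the sources used here, and a breed difference stays open, untested.

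Of 19 T and NK cell markers 7, and of 5 neutrophil markers 3, passed lower in the Chinese wild boar library than in Large White. Neutrophil markers were also lower in Enshi black than in Large White, with 3 of 5 passing, so that part is not particular to the Chinese wild boar library. For Chinese wild boar less residual blood would lower HBB, but HBB had a ratio of 1.78 (1.68 to 1.88) over Large White. The T and NK list had a median ratio of 0.443 and the neutrophil list 0.184. HBB is 1 transcript with 1 library per breed, so it argues against less blood there without excluding it. In Enshi black HBB was 2.80-fold lower (2.58 to 3.05) than in Large White, so less blood stays open for the neutrophil markers there. The 3 erythroid markers together had a median log2 fold of -0.09 in that comparison (bootstrap -1.49 to 1.38), with 1 above 0 and 2 below. None of 19 T and NK cell markers passed in it, and of 9 B and plasma cell markers 3 passed higher and 1 lower. A shift of scaling was excluded as the whole cause for the T and NK list, since it moves all genes alike. The list's median log2 fold differed from that of all expressed genes by -1.17 (bootstrap -1.55 to -0.76, n = 19 genes). Its percentile of 0 among random lists is the value given above, not a separate test. For the neutrophil list the difference was -2.44 (-3.18 to 1.57, n = 5 genes) at percentile 0.01. That range includes 0 because the genes disagreed, with 1 above 0 and 4 below. It measures that disagreement and not a shift of scaling, so 5 genes are too few to decide there. A difference in the immune cells of this animal or breed may remain as a hypothesis, untested with 1 animal.

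In the Enshi black library alone, 47 gene IDs had 3 counts or fewer with at least 5 CPM in both others, and 35 of them (74.5%) had no symbol, against 26.9% of 8640 IDs at that level. The 12 with a symbol were GNB2, FILIP1L, BANF1, ZNF251, ORAI2, PHLDB1, TBRG1, CAPZA2, C2orf68, ARMC10, MRPL55 and GCAT. Reads moved between gene IDs by another annotation or alignment setting may explain it. In Enshi black alone 12 IDs were also present, against at most 3 for another library. Gained IDs were not matched to lost ones, and variants of this breed could also give such IDs. The count therefore does not single out moved reads. Loss of short genes cannot be told apart, with a median RefSeq (Sscrofa11.1) span ratio of 0.416 (0.20 to 1.52, n = 11) and a gap of -0.30 in median log2 fold between the shortest and the longest of 10 groups of genes, along a trend that covers the library, nor can overlapping genes, at 54.5% (23.4 to 83.3) against 35.8%, because 11 genes are too few. GC content was not tested for lack of a genome, and variants of this breed against the reference, and breed itself, stay open, untested.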
